A study of Mus musculus with 8 samples.

How the data were processed

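Total RNA from 8 kidneys, 4 of Akita and 4 of control mice, was labelled with Cy3 and hybridised to one-colour Agilent mouse miRNA arrays, 1 array per sample, with 100 ng of RNA per labelling, per the labels' protocols. The groups and the replicate numbers 1 to 4 were taken from the sample titles, in which the controls are called Mock and which the other labels describe as control mice. All 8 arrays lay on 1 slide and were scanned on 1 date. The deposited scanner files hold spot intensities on a linear scale. Per the file headers, they were extracted with Agilent Feature Extraction 12.0.3.1, which subtracted a fitted spatial surface as background and applied no normalization between arrays; the intensity can be negative after this step. The deposited value table of the series holds a linear ratio per miRNA and array, normalized by the authors: set against the scanner files, each value was Feature Extraction's total signal of the miRNA divided by a factor per array and by the median of that miRNA over the 8 arrays. The steps behind these factors are not given in the sources used here. The medians of its 8 columns ran from 0.70 to 0.97 in the control samples and from 1.03 to 1.22 in the Akita samples, without overlap. This value table was used as an alternative. Probe positions are those of the array annotation, which names the mm9 build. The deposited flags for outlier, saturated and above-background spots were used as given.

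From these files, control spots and spots flagged as outliers were left out (2.03% to 3.02% of the non-control spots per array), and the processed signal was averaged over the spots of each of 4415 probes. No spot was saturated. Each array was divided by its 75th percentile over the 451 probes that were well above background, on at least 0.5 of their spots, on all 8 arrays. The probes of a miRNA, at most 4, were summed on the linear scale, so that a brighter probe weighs more. Of the called miRNAs, 23 had at least 2 bright probes, and in 0 of these did the probes disagree in sign. The probes of a miRNA are mostly shortened forms of the same sequence and were summed for the call, so this agreement is no independent check. Sums under 23.65, the smallest among miRNAs above background on all arrays, were set to that floor (4.56 on the log2 scale), and log2 was taken. Folds of miRNAs near the floor are understated. A miRNA counted as above background on an array if at least 1 of its probes did, and 285 of 1881 miRNAs were tested, those above background on all 4 arrays of at least 1 group. The number of arrays limits the precision, and dim miRNAs have the fewest usable values.

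Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 9.16 total degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 285 miRNAs and a threshold of 0.05. In a simulation of this comparison on 285 miRNAs with 60 changed ones, over 20 runs, 57.5% of changes of 1.25-fold, 90.2% of 1.5-fold and 97.0% of 2-fold were recovered, 3.54% of the calls were false, and 0 calls had the wrong sign. The simulated values varied independently between miRNAs, with no floor, no scaling step and no effect of slide row. These shares hold for that setting only and can differ on the real arrays. A miRNA below background on every array of a group has only a bound there: the mean of the bright group over the mean of, per array, the highest of the floor, the lowest signal above background and its own signal. The floor was added to this bound after a bound above the fitted change was seen, which lowers the bound. The bound concerns the group means and leaves out their sampling error. Lists of miRNAs were fixed before the data were examined: 25 lists, of which 16 had the 3 tested members that a set test needs. These were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the 16 lists. Measures per array were compared with exact two-sided permutation tests over the 35 splits of 8 arrays into 4 and 4, and the smallest p this can give is 0.0286. These p-values were adjusted over the 10 measures compared per array.

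The miRNAs named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called miRNAs whose groups do not overlap, up to 4 members of each list, 11 miRNAs named in advance, and, as bounds, called miRNAs above background in 1 group only. MiR-150-5p, miR-148a-3p, miR-221-3p, miR-222-3p, let-7b-3p and let-7f-1-3p were named after their values were seen. Neighbouring and host genes were taken by name from a RefSeq table of GRCm38.p6, in which 38 of the 42 called miRNAs were found; no coordinates were taken from it.

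Of the 29 alternatives, most changed 1 choice and kept the rest. The deposited value table replaced the probe summary, the scaling and the centring together, and normexp changed the background method along with its offset. The alternatives were 5 other scalings (the percentile over all probes, quantile, median, cyclic loess, none), normexp background correction with an offset of 50, Feature Extraction's total signal per miRNA, other summaries of the probes, 3 other filters on dim miRNAs, a floor 4 times higher, outlier spots kept, other variance models (trend with robust fitting, array weights), the deposited value table, the replicate number as a block, and each of the 8 arrays left out. Scaling by the labelling spike-ins and leaving out the 2 arrays of slide column 4, whose local background was lower, were added after seeing the data, as was subtracting the mean of the negative control spots of each array. Figures were drawn with matplotlib 3.10.9. Neither sequence reads nor measurements outside these arrays were analysed here.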

Results

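MicroRNA levels were measured in whole kidneys of male Akita mice and of age-matched male C57BL/6J controls, with 4 samples in each group and 1 array per sample. Akita mice carry a dominant mutation of the insulin gene Ins2 that makes proinsulin misfold in the pancreatic beta cells, so that they become diabetic while young. The sample titles call the controls Mock, and whether these mice had a mock treatment is not given in the sources used here. The labels give the age for all 8 samples as 36 without a unit. The arrays carry probes for 1881 mouse miRNAs, of which 257 were well above background on all 8 arrays and 1532 on none. The number above background per array ranged from 293 to 327 in the control kidneys and from 274 to 298 in the Akita kidneys. Comparisons were made over the miRNAs that were well above background on all 4 arrays of at least 1 group. Values are log2 scaled signals, given as mean ± SD with n = 4 per group, and a log2 fold change is Akita minus control. The design text asks how the miRNAs of the Akita kidney differ from those of control kidneys. No label says that each sample came from a mouse of its own, so the p-values measure the spread between these samples only.

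Akita kidneys differed from control kidneys in 42 of the tested miRNAs at an adjusted p under 0.05, 24 of them higher in Akita and 18 lower. Among the called miRNAs above background on all 8 arrays, the largest rise was that of miR-34a-5p, a miRNA induced by the tumour suppressor p53. It was 2.48-fold higher in Akita kidneys (10.12 ± 0.10 in control and 11.43 ± 0.16 in Akita, n = 4 each, log2 fold change 1.31 ± 0.09 SE, adjusted p = 5.4e-05). The largest fall among the same miRNAs was that of miR-146a-5p, a miRNA that NF-kappaB induces and that dampens inflammatory signalling. It was 2.40-fold lower (8.77 ± 0.33 and 7.51 ± 0.07, log2 fold change -1.26 ± 0.15 SE, adjusted p = 0.00073). These were the only 2 called miRNAs above background on all 8 arrays that moved by at least 1 on the log2 scale. Called miRNAs below background on some arrays can have understated changes. MiR-210-3p, the standard miRNA of the hypoxia response, was 1.88-fold higher (log2 fold change 0.91 ± 0.16 SE, adjusted p = 0.0072), and miR-193b-3p was 1.67-fold higher (0.74 ± 0.08 SE, adjusted p = 0.00073). In 65 of the tested miRNAs all 4 Akita values lay on the same side of all 4 control values, which is 22.8% where chance gives 2.86%, and 39 of the 42 called miRNAs were among them.

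**Figure D1:**
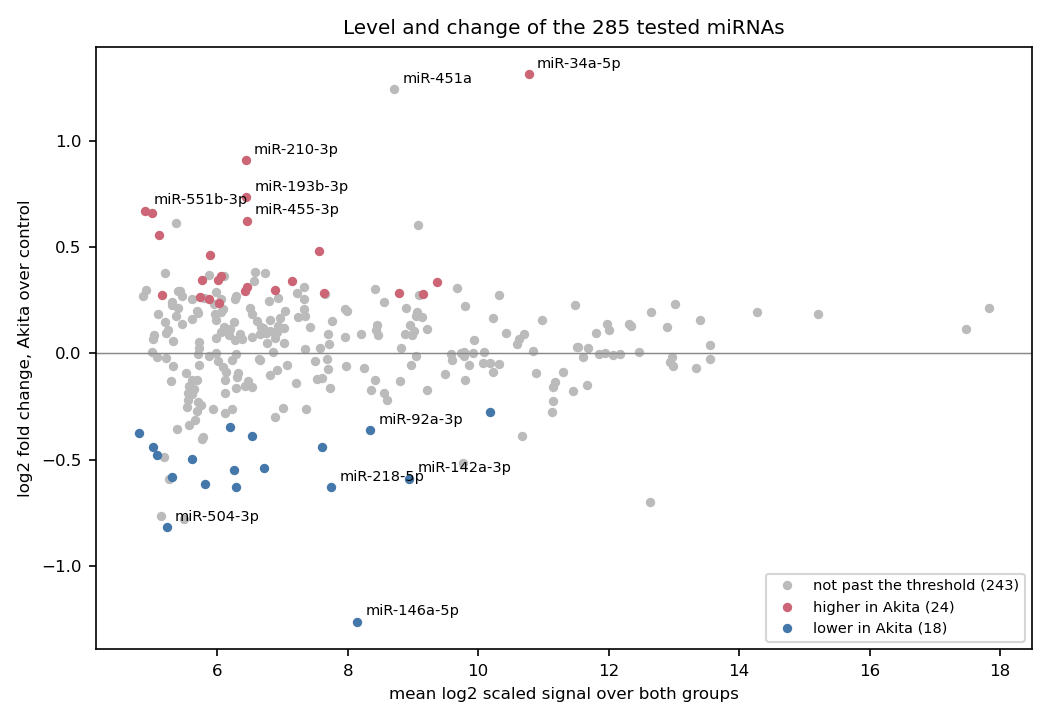
Mean log2 scaled signal over both groups (x axis) against the log2 fold change of Akita over control (y axis) for the tested miRNAs. Red points are the 24 miRNAs higher in Akita at an adjusted p under 0.05, blue points the 18 lower ones and grey points the rest. MiR-34a-5p at 1.31 and miR-146a-5p at -1.26 lie farthest from 0 among the called miRNAs above background on all 8 arrays, and miR-451a at 1.24 is not called. Points of miRNAs below background on some arrays can understate the change.

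The split between higher and lower calls depended on how the arrays were scaled to each other. Before scaling, the Akita arrays were dimmer: the 75th percentile of the probes measured on all 8 arrays was 420.8 ± 35.2 in Akita and 506.7 ± 10.3 in control (SD, n = 4 each), 17.0% lower. Its exact two-sided permutation p = 0.0286 was the smallest that 4 against 4 can give, and the p adjusted over the 10 measures compared per array was 0.0571. With each array divided by its own percentile, the median log2 fold change of all tested miRNAs was 0.06, and it was -0.21 without scaling, -0.18 with the labelling spike-ins as the reference and 0.16 with the percentile taken over all probes. Against the 24 higher and 18 lower calls, there were 5 higher and 104 lower without scaling, 7 and 110 with the spike-ins, 7 and 26 with median scaling and 10 and 4 with the percentile over all probes. All changes below are relative to the 75th percentile of the probes measured on all 8 arrays, not to the median miRNA. The excess of higher over lower calls therefore belongs to this choice of reference. Of the 42 calls, 7, among them miR-34a-5p, miR-146a-5p, miR-193b-3p and miR-210-3p, were made under each of the 6 other scalings.

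The 42 calls also rested on the number of arrays. With 1 array left out, the count was 20 without control replicate 3 or Akita replicate 1, 21 without control replicate 2 or Akita replicate 3, 25 without Akita replicate 2, and from 32 to 36 in the remaining fits. Higher calls numbered 18 without control replicate 1 and from 8 to 12 without any other single array, and without control replicate 4 there were 9 higher and 27 lower. Of the 42 miRNAs, 15 were called in each of the 8 leave-one-out fits, and these included miR-34a-5p, miR-193b-3p, miR-210-3p, miR-149-5p, miR-129-1-3p, miR-146a-5p, miR-155-5p, both arms of miR-142a, miR-342-3p, miR-218-5p, miR-181c-5p, miR-181d-5p, miR-1894-3p and miR-92a-3p. Each of the other calls was lost without at least 1 array, that of miR-34b-5p only without control replicate 3 (adjusted p = 0.052, with a range over its alternatives from 0.00068 to 1). All control arrays lay in row 1 of the slide and all Akita arrays in row 2, so that slide row and group cannot be told apart.

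MiRNAs of leukocytes fell in the Akita kidneys. Of the 10 listed members 7 were tested, and 6 were lower past the threshold, with none higher; adjusted over the list alone, all 7 were lower. MiR-155-5p, which activated lymphocytes and macrophages express, was 1.53-fold lower (log2 fold change -0.61 ± 0.06 SE, adjusted p = 0.00067). MiR-142a-3p, a miRNA of nearly all blood cell lineages, was 1.51-fold lower (-0.59 ± 0.09 SE, adjusted p = 0.0051), and its other arm, miR-142a-5p, was 1.46-fold lower (adjusted p = 0.0091). MiR-342-3p was 1.45-fold lower (adjusted p = 0.0047) and miR-223-3p, the main miRNA of neutrophils and monocytes, 1.36-fold lower (adjusted p = 0.034). The lymphocyte miRNA miR-150-5p had a log2 fold change of -0.35 with an adjusted p = 0.090. The list had a median log2 fold change of -0.55, negative under all 29 alternatives (from -0.82 without scaling to -0.14 with normexp background correction). Its camera test gave an adjusted p = 7.3e-08 with the preset correlation and an adjusted p = 0.18 with an estimated correlation, and fry gave an adjusted p = 0.0013. Fewer members were called with the percentile over all probes (1), with normexp (2), with the floor 4 times higher (3) and with no filter on dim miRNAs (1 of then 10 tested). MiR-146a-5p and miR-155-5p are also made by other cells than leukocytes.

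The erythrocyte miRNA miR-451a, the only tested one of the 6 listed, varied between the control kidneys. It had log2 signals of 6.44, 8.61, 10.23 and 7.08 in the 4 control kidneys and between 9.18 and 9.59 in the Akita kidneys. Its log2 fold change of 1.24 ± 0.69 SE was not past the threshold (adjusted p = 0.24), and without control replicate 3 it was called, with a log2 fold change of 1.94 (adjusted p = 0.028, the lowest over its alternatives, which reached 0.62). The mean of the 7 leukocyte members lay between 7.19 and 7.39 in the control kidneys and between 6.56 and 6.77 in the Akita kidneys.

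**Figure D2:**
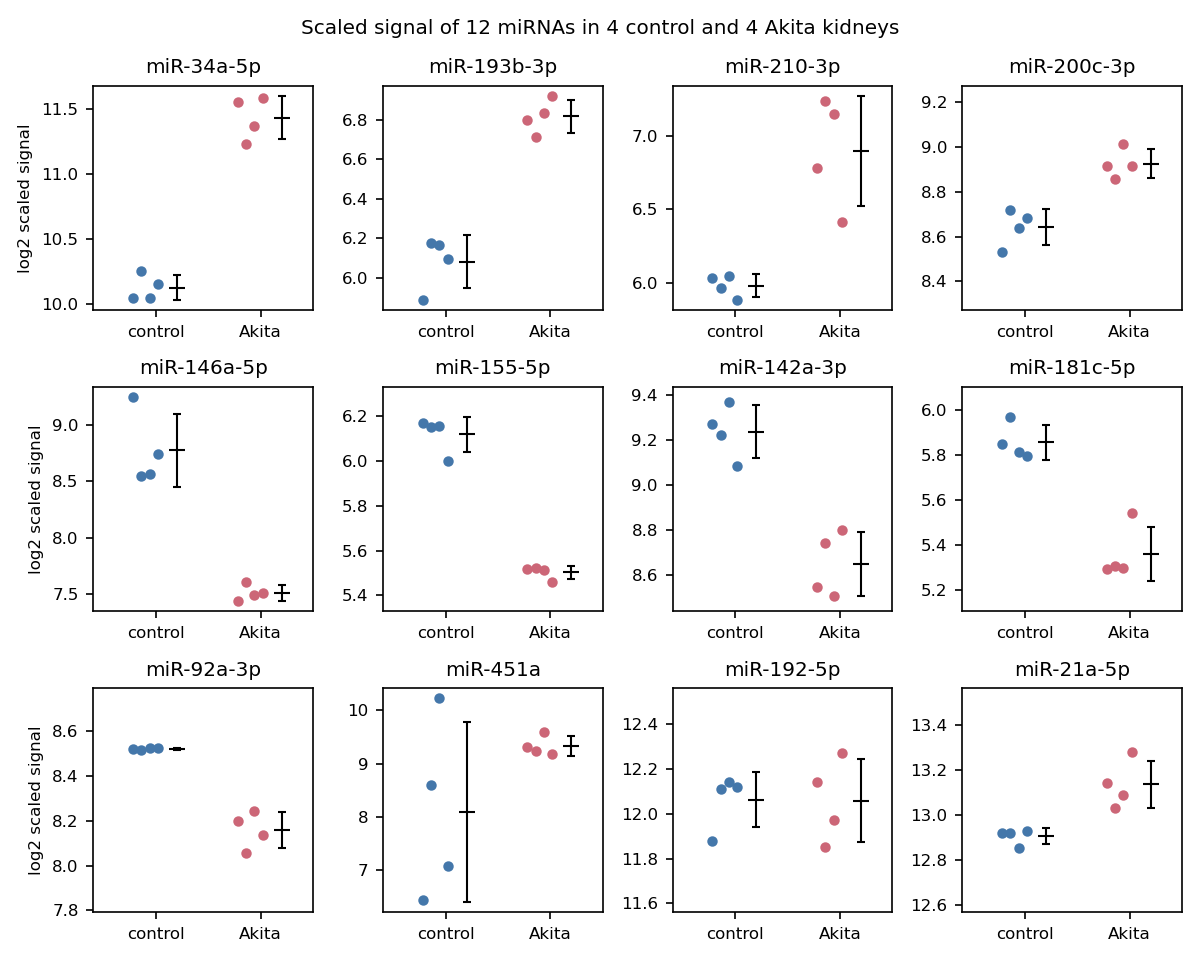
Log2 scaled signal (y axis, a separate range in each panel) of 12 miRNAs on the 4 control arrays (blue) and the 4 Akita arrays (red); each point is 1 kidney, and the bars give the mean and SD of the 4. MiR-34a-5p, miR-193b-3p, miR-210-3p and miR-200c-3p lie higher in all 4 Akita kidneys than in any control kidney, miR-146a-5p, miR-155-5p, miR-142a-3p, miR-181c-5p and miR-92a-3p lower, and the control values of miR-451a run from 6.44 to 10.23.

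Among the miRNAs that rose, both measured members of the p53-responsive miR-34 family were called. Next to miR-34a-5p, miR-34b-5p was 1.27-fold higher (log2 fold change 0.35 ± 0.06 SE, adjusted p = 0.0068), and that call was lost without scaling (0.07), with the spike-ins (0.10), with median scaling (0.24) and with the percentile over all probes (0.44). The single tested member of the hypoxia list was miR-210-3p, named above. Both arms of miR-455 were higher, the 3p arm by 0.62 ± 0.15 SE (adjusted p = 0.027) and the 5p arm by 0.56 ± 0.12 SE (adjusted p = 0.018), although the 5p arm was above background on 2 of the 4 control arrays, so that the size of its change is uncertain. MiR-149-5p was 1.38-fold higher (adjusted p = 0.0058), miR-129-1-3p, above background on 3 of the 4 control arrays, 1.58-fold higher (adjusted p = 0.0068), miR-6412 1.40-fold higher (adjusted p = 0.017), and miR-702-3p and miR-8101 1.27-fold higher (adjusted p = 0.018 and 0.039). MiR-551b-3p was well above background on all 4 Akita arrays and on no control array. Its log2 difference of means was at least 0.66 (adjusted p = 0.017). All 4 control values stood at the floor of 4.56, so that they add no measured spread to that p-value. The confidence interval of the fitted change ran from 0.35 to 0.99. It was called under 23 of its 28 alternatives and in 6 of the 8 leave-one-out fits, with changes from 0 to 3.49 over the alternatives.

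In the miR-200 family, which keeps tubular epithelial cells in their epithelial state, 3 of 6 tested members rose and none fell. MiR-200c-3p was 1.22-fold higher (log2 fold change 0.28 ± 0.07 SE, adjusted p = 0.032), miR-141-3p 1.21-fold higher (adjusted p = 0.047) and miR-200b-5p 1.18-fold higher (adjusted p = 0.047), while miR-429-3p at 0.15 and miR-200b-3p at 0.14 were not called. The camera test of the family missed the threshold (adjusted p = 0.13 with the preset and 0.87 with an estimated correlation), and fry gave an adjusted p = 0.035. The family's median of 0.20 turned to -0.08 without scaling and to -0.05 with the spike-ins. Its number of higher members was 2 under quantile scaling, 2 under cyclic loess and 0 under the remaining scalings, and the call of miR-200c-3p was lost without each single array.

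In the fibrosis-linked list, 1 of 7 tested members, miR-34a-5p, was called, and 2 adjusted over the list alone. The second was miR-21a-5p, the miRNA most often tied to renal fibrosis, which stood at 12.90 ± 0.04 in control and 13.14 ± 0.11 in Akita (log2 fold change 0.23 ± 0.07 SE) and missed the threshold over all miRNAs at an adjusted p = 0.059, with all 4 Akita values above all 4 control values; its sign turned without scaling (-0.04) and with the spike-ins (-0.01). MiR-214-3p at 0.18 and miR-212-3p at 0.21 were not called. The median of the list was 0.18, and it was negative without scaling and with the spike-ins. Its camera test gave an adjusted p = 0.13 and fry an adjusted p = 0.062.

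The miR-181 family, which is known from lymphocyte development, fell. Of 4 tested members 3 were lower and none higher, over all miRNAs and adjusted over the list alone alike. MiR-181c-5p was 1.41-fold lower (-0.50 ± 0.08 SE, adjusted p = 0.0052) and miR-181b-5p 1.27-fold lower (adjusted p = 0.034). MiR-181d-5p, below background on all 4 Akita arrays, had a log2 difference of means of at most -0.32 (adjusted p = 0.0097). The confidence interval of its fitted change ran from -0.54 to -0.21. The median of the family was -0.36, and -0.33 with miR-181d-5p at the bound of -0.32. MiR-181a-5p stood at -0.18 (adjusted p = 0.18). Camera gave an adjusted p = 0.0019 with the preset correlation and an adjusted p = 0.20 with an estimated correlation, and fry an adjusted p = 0.0024. With normexp background correction the 3 called members had log2 fold changes of 0.014, 0.0086 and 0.095, and no call.

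Of the miR-17-92 cluster and its paralogs, which promote cell proliferation, 2 of 10 tested members were lower and none higher; 4 were lower adjusted over the list alone. MiR-92a-3p was 1.29-fold lower (-0.36 ± 0.06 SE, adjusted p = 0.0068) and miR-19b-3p 1.21-fold lower (adjusted p = 0.034), with miR-17-5p at -0.25 (adjusted p = 0.055) and miR-20b-5p at -0.22 (adjusted p = 0.081). Camera gave an adjusted p = 0.0033 for the list, with a median of -0.16, and an adjusted p = 0.87 with an estimated correlation; fry gave an adjusted p = 0.073. With the percentile over all probes the list's median was -0.06 and camera missed the threshold (adjusted p = 0.13, the highest over its alternatives, of which the lowest was 9.4e-15), and with normexp the median was 0.01. Without Akita replicate 4 miR-17-5p and miR-20b-5p were called as well.

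Further falls were those of miR-218-5p, which was 1.55-fold lower (log2 fold change -0.63 ± 0.09 SE, adjusted p = 0.0042), and of miR-10a-3p, 1.31-fold lower (adjusted p = 0.036) and the single called member among 6 tested of the HOX cluster and kidney-enriched list, whose median was -0.09 and turned positive with the percentile over all probes; the call held adjusted over the list alone and was lost without most single arrays. MiR-504-3p and miR-1894-3p were below background on all 4 Akita arrays. Their log2 differences of means were at most -0.77 and -0.58 (adjusted p = 0.038 and 0.010). The confidence intervals of their fitted changes reached up to -0.33 for both. MiR-504-3p was called under 13 of its 28 alternatives, among them the 6 other scalings, and in 2 of the 8 leave-one-out fits. MiR-1894-3p was called under 24 of 28 and in all 8, but stood at 0.030 with normexp. MiR-8102 was lower (log2 fold change -0.44, adjusted p = 0.024), and it was above background on 2 of the 4 Akita arrays, so that the size of its change is uncertain. Of the neuronal list, 1 of 2 tested members, miR-9-3p, had a log2 fold change of -0.48 (adjusted p = 0.049), also adjusted over the list alone, and it was above background on 1 Akita array. The size of that change is uncertain and the groups overlapped. MiR-9-3p was called under 7 of its 28 alternatives and in 2 of the 8 leave-one-out fits.

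**Figure D3:**
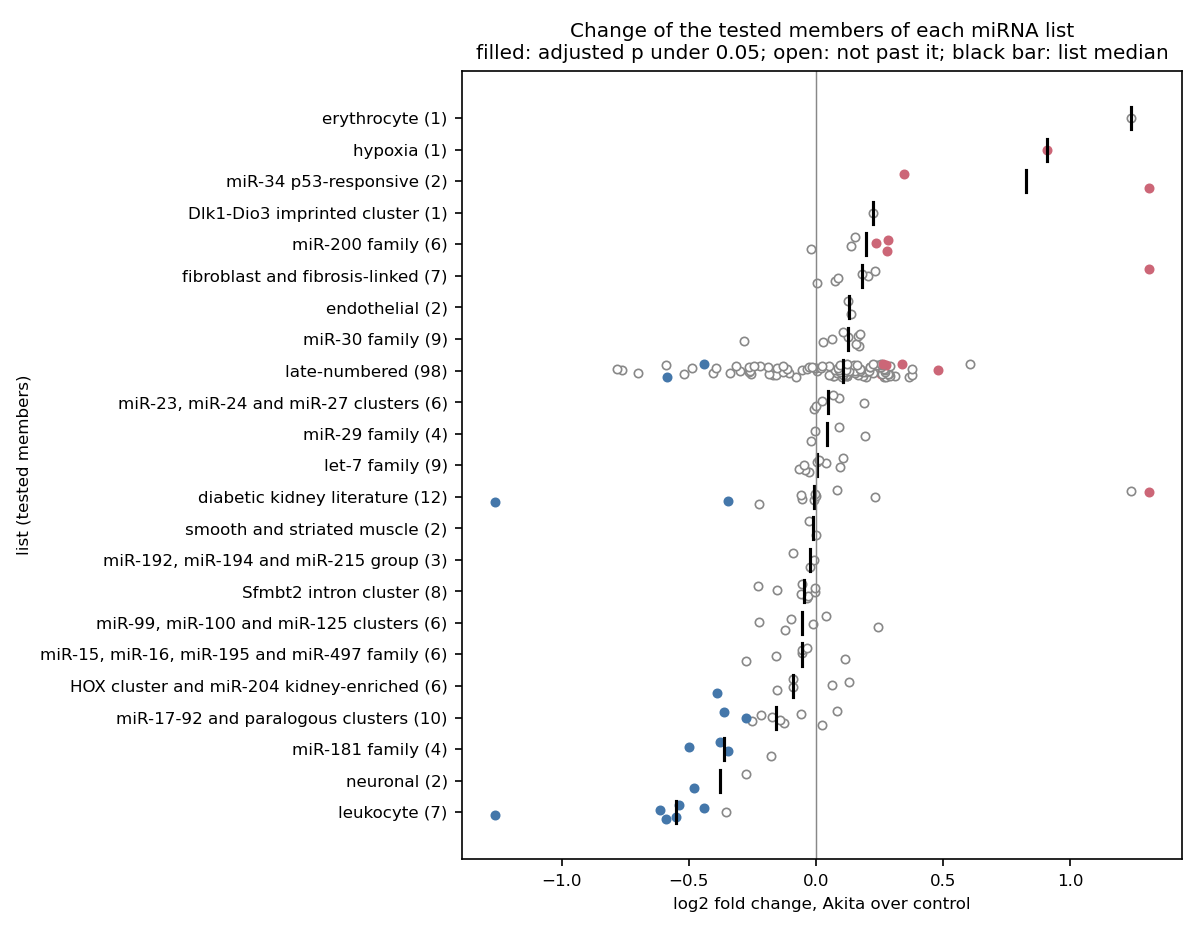
Log2 fold change of Akita over control (x axis) for the tested members of each miRNA list (y axis, number of tested members in brackets). Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the list median; 6 of the 7 leukocyte members are filled and lower, and the leukocyte median is -0.55.

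Several miRNA families of the kidney showed no call among their listed members. In the miR-192, miR-194 and miR-215 group, enriched in the tubular epithelium, none of 3 tested members was called: miR-192-5p stood at 12.06 ± 0.12 in control and 12.06 ± 0.18 in Akita (log2 fold change -0.01, 95% interval -0.25 to 0.23), and miR-194-5p had a log2 fold change of -0.09. None of the 9 tested members of the miR-30 family, the 4 of the miR-29 family or the 9 of the let-7 list was called, with median log2 fold changes of 0.12, 0.04 and 0.01. The let-7 list holds miR-98 and let-7 5p arms only. Outside it, let-7b-3p (0.31, adjusted p = 0.039) and let-7f-1-3p (0.29, adjusted p = 0.049), named after their values were seen, were called higher; under the 29 alternatives both stayed positive and were called in 10 and 5, and neither call was kept without scaling, with the spike-ins, with median scaling or with the percentile over all probes. Of the fits without 1 array, only that without control replicate 1 kept the call of let-7b-3p, and none kept that of let-7f-1-3p. MiR-30a-5p stood at 13.32 ± 0.06 and 13.47 ± 0.08 (0.16, adjusted p = 0.14), miR-29c-3p at 12.18 ± 0.07 and 12.17 ± 0.15 (0.00), and miR-200b-3p at 11.91 ± 0.09 and 12.05 ± 0.11 (0.14, adjusted p = 0.26). MiR-10a-5p had a log2 fold change of -0.15 (adjusted p = 0.16). The median of the let-7 family was above 0 while its camera test, not past the threshold, pointed down. All of these family medians changed sign under some scalings; those of the miR-30 and miR-29 families were negative without scaling and with the spike-ins. With the spike-ins, miR-192-5p, miR-194-5p and miR-29c-3p were called lower (-0.26, -0.34 and -0.25).

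Of 16 miRNAs that the literature ties to the diabetic kidney, 12 were tested: miR-34a-5p rose, miR-146a-5p and miR-181b-5p fell, and 9 were not called. Adjusted over the list alone, 2 rose and 3 fell, and the median of the list was -0.01 while its mean was 0.08. Neither camera (adjusted p = 0.53) nor fry (adjusted p = 0.87) gave the list a direction, and fry's test for changes in either direction gave an adjusted p = 4.9e-06. That test was also past the threshold for the leukocyte list (adjusted p = 0.00011), the fibrosis-linked list (0.00016), the miR-17-92 (0.0011), miR-200 (0.0031), miR-181 (0.018) and miR-30 (0.021) families and the miRNAs with late miRBase numbers (0.0038). It asks whether members changed at all, not whether they changed more than other miRNAs. With 97 of the tested miRNAs at an unadjusted limma p under 0.05, a few changed members can carry a list past it. Of the miR-15, miR-16, miR-195 and miR-497 family, of the miR-23, miR-24 and miR-27 clusters, and of the miR-99, miR-100 and miR-125 clusters, none of 6 tested members each was called. The same held for the 8 tested members of the Sfmbt2 intron cluster and the 1 of the Dlk1-Dio3 cluster, miR-494-3p at 0.23, which passed adjusted over the list alone. Among the 98 tested miRNAs with a miRBase number above 1000, many of them annotations of low confidence, 5 rose and 2 fell, and adjusted over the list alone 0 did.

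Markers of other cell types gave no call beside the leukocyte and neuronal lists. The endothelial miR-126a-3p stood at 12.24 ± 0.06 in control and 12.38 ± 0.15 in Akita (log2 fold change 0.14, adjusted p = 0.28), and its 5p arm at 0.12. The smooth muscle miRNAs miR-143-3p and miR-145a-5p had log2 fold changes of 0.00 and -0.03; without scaling both were called lower (-0.27 and -0.30), and with the spike-ins miR-145a-5p was (-0.27). No listed miRNA of pancreas and islets or of liver was well above background in enough arrays to be tested.

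The probes of the leading miRNAs map to these places in the mm9 build, as the array annotation gives them. The miR-34a-5p probe lies on chromosome 4 from 149442585 to 149442603 and that of miR-210-3p on chromosome 7 from 148407355 to 148407369. MiR-193b-3p lies on chromosome 16 from 13449669 to 13449684, and miR-155-5p on the same chromosome from 84714394 to 84714410, within its non-coding host gene Mir155hg. MiR-146a-5p lies on chromosome 11 from 43187908 to 43187925, and miR-142a-3p from 87756904 to 87756925. MiR-218-5p has copies on chromosome 5 from 48615206 to 48615225 and on chromosome 11 from 35430343 to 35430362, within the genes Slit2 and Slit3. MiR-455 lies within Col27a1, miR-149 within Gpc1, miR-342 within Evl and miR-10a within Hoxb3. Members of a family that differ by few bases (the let-7, miR-181, miR-200 and miR-17 families) can bind each other's probes, so that their values are not fully separate.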

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

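The comparisons with residual blood, with a common share of leukocytes and with the spike-ins, and the view of the slide row, were chosen only after the result was seen; the other tests were planned before. The tests of a common share of leukocytes replaced a comparison of miR-146a-5p with miR-142a alone that had pointed the same way.

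In several groups of 4, 1 sample lay far from the other 3, by a gap to the nearest of them that takes up most of the group's range; 188 groups were looked at, chance alone gives about 1 in 20 of them, or 9.4, and 11 were found. Akita replicate 4 stood apart for 4 miRNAs: miR-155-5p (5.46 against 5.51 to 5.52, ratio 0.903), miR-181c-5p (5.54 against 5.29 to 5.31, ratio 0.946), miR-214-3p (6.85 against 6.52 to 6.58, ratio 0.835) and miR-181d-5p (4.76 against 3 values at the floor of 4.56, ratio 1). Control replicate 1 stood apart for miR-455-3p (5.78 against 6.22 to 6.29, ratio 0.866), miR-192-5p (11.88 against 12.11 to 12.14, ratio 0.902) and miR-10b-5p (11.21 against 11.37 to 11.40, ratio 0.845). Control replicate 4 stood apart for miR-155-5p (6.00 against 6.15 to 6.17, ratio 0.90) and for its local background (39.1 against 44.8 to 45.6, ratio 0.877), and control replicate 2 for miR-143-3p (9.94 against 9.64 to 9.68, ratio 0.89). The lower local background was shared by slide column 4, where Akita replicate 4 read 36.8. Outside these groups, control replicate 4 alone was extracted with an effective feature size of 0.7943, against 0.6 on the other arrays. What that difference did to the signals was not tested. The labelling spike-ins of Akita replicate 1 read 1843 against 1676 to 1680 on the other Akita arrays (ratio 0.976).

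The count of 42 miRNAs past the threshold was set against other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, called as many as 42, and the highest of the others called 7. The smallest exact permutation p that such splits can give is 0.0286, so that chance is unlikely but not excluded. The real split is also the split by slide row, so the count cannot tie the calls to the Akita genotype.

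The lower leukocyte miRNAs of the Akita kidneys were weighed against technical explanations. Scaling between arrays is argued against for the direction: the list's median log2 fold change stayed at or below -0.46 under all 6 scalings. With the percentile over all probes, however, only 1 of the 7 members was called. The median stayed at or below -0.51 without each of the 8 arrays, so no single kidney carried it. Background treatment moved it more: the median was -0.14 with normexp (2 members called) and -0.59 with the negative controls subtracted (6 called). Background was not tested as an explanation of the list and stays open. Less blood left in the Akita kidneys would lower miR-451a, the single erythrocyte miRNA tested, which instead stood 2.59 of its standard errors above the leukocyte median. These are limma's moderated standard errors, and the leukocyte median was taken as free of error, so that the distance can be overstated. Within the control kidneys miR-451a spanned 3.80 log2 units while the leukocyte mean spanned 0.20. One lower share of leukocytes would lower all members equally. The 7 members' changes had an SD of 0.30, and only 1 of the 35 splits, the real one, spread them as widely (highest other 0.24). The exact p of this spread over the splits was 0.0286, the smallest possible. It speaks against an equal fall of all 7, but the width rests on miR-146a-5p, which other cells than leukocytes also make. The test therefore cannot decide whether the share of leukocytes was lower. Without miR-146a-5p the SD was 0.10, which 8 of the 35 splits reached, so that a smaller share of leukocytes may account for the other 6, as may lower expression within cells, and neither can be told from the slide row or from the Akita genotype.

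The Akita arrays were dimmer than the control arrays by a log2 ratio of -0.27 in the 75th percentile. Weaker labelling or hybridisation is argued against by the labelling spike-ins, whose log2 ratio was -0.0249; the percentile over the spike-ins was 0.245 ± 0.019 in Akita and 0.290 ± 0.003 in control, with no overlap. The row of the slide stays open, since 0 of its 2 rows held arrays of both groups. A smaller share of miRNA in the total RNA of the Akita kidneys, from the genotype or from the extraction, may also lie behind it and was not tested; the spike-ins enter with the labelling and cannot show a loss before it.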

How the results depend on the processing

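Scaling by the labelling spike-ins, leaving out slide column 4 and subtracting the negative controls were chosen after the result was seen. Against 42 calls (24 higher, 18 lower), the percentile over all probes gave 14 (10 and 4), no scaling 109 (5 and 104), spike-in scaling 117 (7 and 110), cyclic loess 64 (32 and 32), normexp 89 (81 and 8), array weights 76 (48 and 28), no filter on dim miRNAs 6 (4 and 2) and the higher floor 9 (4 and 5). Median scaling gave 7 higher, total gene signal 13 higher and 29 lower, and the arrays without slide column 4 gave 7 higher. No filter raised the miRNAs tested to 1881; for the other settings the cause was not tested. Leaving out 1 array gave 20 to 36 calls, 8 to 18 higher and 11 to 27 lower. Quantile scaling (62), the deposited value table (36) and the subtraction of the negative controls (31, with 16 higher) stayed within 1.5 times.

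The replicate numbers equal the slide columns, so that the replicate block is also a block by column. Same-numbered arrays correlated at 0.10, -0.30, 0.34 and -0.35 in their deviations from the group means. Of the 8 arrays, 1 correlated best with its own number. The correlations had no common sign, but so few of them cannot exclude a pairing. Local background was lowest in column 4 in both groups (39.08 in control and 36.79 in Akita). With the replicate block 25 miRNAs were called, 11 of them higher.

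Among the named miRNAs called in the fit reported or in the alternative, signs turned without scaling for miR-200b-5p (-0.035), miR-143-3p (-0.27, called) and miR-24-3p (-0.25, called); with the spike-ins for miR-200b-5p (-0.0090), miR-27a-3p (-0.16, called) and miR-24-3p (-0.22, called); and with normexp, with no call, for miR-1894-3p (0.030), miR-181c-5p (0.014), miR-8102 (0.080), miR-10a-3p (0.055), miR-181b-5p (0.0086), miR-9-3p (0.077) and miR-181d-5p (0.095). Among those called in neither, signs turned for 22 without scaling, 22 with the spike-ins, 12 with the percentile over all probes, 11 with normexp and at most 9 under any other alternative. Over the named miRNAs and lists and all alternatives, 2513 values were the same, 347 lost the call, 126 gained it, and the rest moved otherwise. Same means an equal sign and call for a miRNA and an equal camera direction and call for a list. For a count of called list members it means within 1.5 times. Values called in neither fit with an unchanged sign are among the same. MiR-34a-5p and miR-193b-3p were called under all 29 alternatives. The limit from signal is at the dim end: 1532 of 1881 miRNAs were above background on no array.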

Other observations

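The refit with the negative controls subtracted was chosen only after the result was seen; the comparison of dim and bright miRNAs was planned before.

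MiR-221-3p and miR-222-3p, which lie within 10 kb of each other on the X chromosome (in mm9, probes from 18723483 to 18723501 and from 18724075 to 18724087) and act on cell cycle inhibitors, were 1.26-fold and 1.22-fold higher in Akita kidneys (log2 fold changes 0.33 ± 0.08 SE and 0.28 ± 0.07 SE, adjusted p = 0.034 and 0.036), with all 4 Akita values above all 4 control values in both. Both were named after their values were seen, were positive under all 29 alternatives and called under 13 of them; their calls were lost without all single arrays but Akita replicate 2. MiR-148a-3p was 1.55-fold lower (-0.63 ± 0.16 SE, adjusted p = 0.034), negative under all 29 alternatives and called under 19, although the groups overlapped and the call was lost without control replicates 1, 2 and 3 and Akita replicates 1 and 3; it too was named after its values were seen.

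The 10 brightest miRNAs made up 73.0% ± 0.4 of the summed signal in control and 74.8% ± 1.1 in Akita (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible, and 0.0571 adjusted over 10 measures). Negative control spots read 40.9 ± 0.8 in control and 39.7 ± 0.5 in Akita before background subtraction (exact two-sided permutation p = 0.0286, adjusted 0.0571).

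If background left in dim miRNAs had shifted them under the lower brightness of the Akita arrays, their changes would lie above those of bright ones. The median log2 fold change was 0.07 in the dimmest tertile of the tested miRNAs and 0.02 in the brightest, a gap of 0.044, which was 0.0073 after the negative control level was subtracted, 0.060 with quantile scaling and 0.16 with normexp background correction. A gap within 0.05 had been set beforehand as speaking against such a shift, but these medians run over miRNAs that go both ways (55.8% of the dimmest tertile were higher in Akita) and decide nothing about the calls. Refitted with the negative control level subtracted, 31 miRNAs were called, all among the 42, with 16 higher in place of 24 and 15 lower in place of 18. Of the 24 higher calls, 16 had a level under 6.5 in control, and of the 18 lower calls 10 had one of at least 6.5. Among the lost calls, let-7f-1-3p had a log2 fold change of 0.29 before and after, and miR-200b-5p 0.24 before and 0.22 after. Both are rises and do not stand for the rest of the lost calls. Whether background lies behind the lost calls stays open.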
